A study of Blumeria hordei with 12 samples.

How the data were processed

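Conidia of Blumeria graminis f. sp. hordei were taken after 2 h and after 4 h 45 min from glass that carried 5% (n/n) n-hexacosanal or carried n-hexacosane, per the labels' protocols. Whether n-hexacosane had the same concentration is not clear from the labels. Slides were kept dark, at 90% humidity and a temperature of 20 °C. RNA was extracted with phenol and chloroform and precipitated with lithium chloride, and strand-specific libraries with inserts of 150 to 400 bp were sequenced, per the labels' protocols. Each of the 4 groups had 3 libraries. Nothing in the sources used here says that replicates came from separate cultures, so p-values measure only the spread between these libraries.

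The deposited table held expected counts per annotated gene and library, in the sense orientation and with gene models named EF1 from Ensembl, per the file headers and attributes. The aligner, the counting tool and the version of the assembly are not given in the sources used here, and no genome sequence was used, so positions are those of the file's own contigs. The table listed 6472 genes on 156 contigs, 6470 of them protein coding and 2 for the RNA of RNase MRP. Of its values, 55.5% were fractional (tolerance 1e-06) and 96.85% were multiples of a sixth, as arises when a read is divided over several positions or features. The authors' rule for this division is not given in the sources used here, so genes of families with similar copies are reported as uncertain. Genes without that remark can hold divided reads too. Values of the choline transporter bgh04430 and the Myb transcription factor bgh02243, for example, were fractional in all 12 libraries. Only 8 genes overlapped another on the same strand, and the share of fractional values there was 65.6%, against 55.4% elsewhere. Reads in the antisense orientation were not analysed here. An informative description was paired with 5072 genes in the table, and 1400 had none; gene names are those of the table.

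Counts were rounded, and genes were kept by edgeR's filterByExpr with the groups as design, which left 5961 genes for testing and removed 511. Library sizes were scaled by TMM factors, and a model with 1 mean per group (8 residual degrees of freedom) was fitted to all 12 libraries by edgeR 4.0.16 in R 4.3.3. Quasi-likelihood tests compared the surfaces at 2 h, the surfaces at 4 h 45 min, the times on hexacosanal, the times on hexacosane, the interaction of surface and time, and the surfaces averaged over both times. P-values were adjusted by Benjamini-Hochberg over the genes tested within each comparison, and genes with an adjusted p under 0.05 were called. A surface difference is hexacosanal minus hexacosane, a time change is 4 h 45 min minus 2 h, and the interaction is the surface difference at 4 h 45 min minus that at 2 h. Errors of log2 values, written SE, are the absolute log2 value divided by the square root of its quasi-likelihood F statistic. They approximate a standard error and are less certain for large changes or low counts. CPM are means of counts scaled to 1e6 per TMM-adjusted library size, with the SD over 3 libraries. A single gene in an exact rank test of 3 against 3 libraries cannot go below p = 0.1, so tests rest on the spread pooled across genes.

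Gene lists were defined by words in the descriptions and tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with adjustment over the lists of at least 5 tested genes. For each list the text gives the genes that passed over all genes tested and, in parentheses, those adjusted over the list alone. None of the camera results passed when the correlation was estimated from the residuals; that value is printed beside each. The word pattern of the signalling list also took every description with a word ending in "ing protein", and narrowed or split lists were added after the descriptions had been read. The list of host plant genes matched 0 genes and was not tested.

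The groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups (within each time for the average; not demanded for the interaction). Of these it took the 12 largest rises and 12 largest falls among genes with an informative description and the largest among the others, together with up to 4 genes with the smallest p of each list; the text names a part of them.

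The alternatives were DESeq2 size factors, library totals without scaling, the Wald test of DESeq2 1.42.0, limma-voom, no filter or a stricter filter of 50 counts, a fit of only the groups compared, replicate number as a block, unrounded values, removal of the 20 most abundant genes, a minimum change of 2-fold, other list tests, and each library left out in turn. Principal components and correlations used log2 CPM. The gene and list tests were first run on simulated counts for 5948 genes, drawn from the means and library sizes of the real ones, with known changes. Only a small share of the genes was changed, all above a minimum level and only on hexacosanal at 2 h. In the surface comparison at 2 h, 74.6% of 67 genes changed 1.5-fold, 95.5% of 67 changed 2-fold and 100% of 66 changed 4-fold were recovered, and 9 of 189 calls were unchanged genes. For the interaction these were 40.3%, 80.6% and 97%, with 5 false calls of 150. In the surface comparison at 4 h 45 min, simulated without changes, 0 genes were called by edgeR.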

Results

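RNA was measured by strand-specific sequencing in conidia of the barley powdery mildew fungus Blumeria graminis f. sp. hordei, an obligate biotroph, on coated glass without a host plant. The glass carried either n-hexacosanal, a very-long-chain aldehyde of plant wax that the labels call inductive, or n-hexacosane, the alkane of the same chain length, which they call non-inducing. Conidia stayed on each surface for 2 h or for 4 h 45 min, which gave 4 groups of 3 libraries and 12 libraries in all. The labels do not make clear whether the alkane had the same concentration as the aldehyde. A difference between the surfaces therefore does not separate the compound from its concentration. The table held reads in the sense orientation for 6472 genes. Total counts per library were 3449615, 2697954 and 3445381 for replicates 1 to 3 on hexacosanal at 2 h, and 2848688, 2621869 and 2858836 on hexacosanal at 4 h 45 min. On hexacosane they were 2683621, 4351094 and 2658307 at 2 h, and 4907234, 3155800 and 2628919 at 4 h 45 min. The 20 most abundant genes took 9.13 ± 0.81% (SD, n = 3) of the counts on hexacosanal at 2 h and 11.06 ± 0.12% at 4 h 45 min, against 7.88 ± 0.49% and 8.38 ± 0.09% on hexacosane.

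The surface separated the libraries more than the time did. The first principal component of log2 CPM (counts scaled to 1e6 per library) held 67.9% of the variance and put all 6 hexacosanal libraries below all 6 hexacosane libraries. The second held 16.7%. Replicate 1 on hexacosanal at 2 h scored −14.2 on the first component, closer to the hexacosane libraries than replicates 2 and 3 at −24.5 and −27.1. Correlations of log2 CPM between libraries, taken across genes, which are not independent replicates, ranged from 0.981 to 0.993 within groups and from 0.866 to 0.985 between groups. The biological coefficient of variation fitted over all groups was 9.8%. The trimmed-mean (TMM) factors that scale library sizes were 0.89 ± 0.04 (SD, n = 6) on hexacosanal and 1.13 ± 0.02 on hexacosane, so levels across surfaces are stated relative to the other genes. Scaling by library totals alone shifted the log2 differences by −0.31 for the surface at 2 h, −0.39 for the surface at 4 h 45 min and −0.35 for both times averaged. The time effects shifted by −0.10 on hexacosanal and −0.02 on hexacosane.

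**Figure D1:**
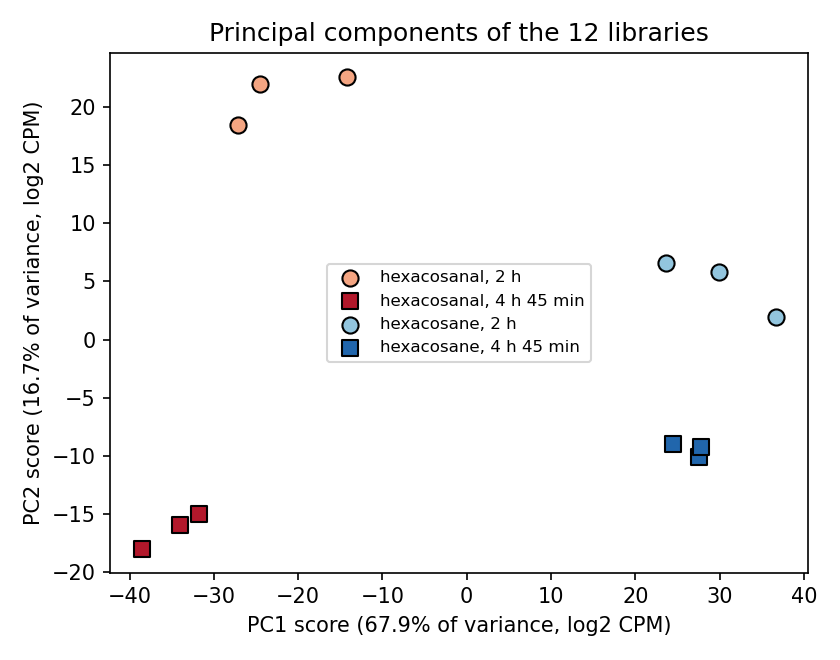
Scores of the 12 libraries on the first and second principal components of log2 CPM; each point is a library, with colour and marker giving surface and time. The horizontal axis holds 67.9% of the variance and separates the surfaces, and the vertical axis holds 16.7%.

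The comparison of the surfaces at 2 h asked which transcripts an inductive wax aldehyde alters early, before the fungus would penetrate a host. The endochitinase gene Chi1 (bgh00059; contig HF943533, 1655586 to 1657093) stood 10.09-fold higher on hexacosanal (log2 difference 3.33 ± 0.42 SE, adjusted p = 8.38e-06, n = 3 per group), at 8298.3 ± 2204.9 CPM (SD) against 820.9 ± 585.6 CPM. A cutinase gene (bgh00227), for an enzyme class that opens the plant cuticle, was 5.18-fold higher (2.37 ± 0.16, adjusted p = 2.74e-08), with 426.1 ± 8.5 CPM against 81.2 ± 25.5 CPM. The homologue of the appressorium genes Egh16 and Gas1 (bgh01420; contig HF943551, 113498 to 115078) was 4.47-fold higher (2.16 ± 0.14, adjusted p = 1.67e-08). It belongs to a family with similar copies that could share reads, so its values here and in the other comparisons are uncertain. In the opposite direction, the glyoxal oxidase gene (bgh00311; contig HF943513, 1000089 to 1002618), whose product class forms hydrogen peroxide, was lower (−1.67 ± 0.11, adjusted p = 2.16e-08), with 1065.2 ± 74 CPM against 3378.7 ± 130.4 CPM.

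Among genes with an informative name, an aquaporin gene (bgh00516) had the largest increase at 2 h, 3.54 ± 0.48 on the log2 scale (SE, n = 3 per group). Other large increases were those of a choline transporter (bgh04430, 3.38 ± 0.40), a sugar transporter (bgh00500, 3.33 ± 0.38), a low-affinity copper transporter (bgh04933, 3.27 ± 0.41) and an ABC transporter (bgh02641, 3.17 ± 0.34). The list of transporters did not pass at 2 h (camera adjusted p = 0.744), with 52 of 159 higher and 49 lower (53 and 49 adjusted over the list alone; 35 and 76 under library totals). A metalloreductase gene (bgh01880), of a class that reduces metal ions before uptake, was higher by 3.25 ± 0.37. Genes for a Ras family protein (bgh05774), the vacuolar sorting protein VPS62 (bgh02411) and the candidate effector CSEP0088 were higher by 3.37 ± 0.37, 3.16 ± 0.35 and 3.17 ± 0.35. CSEP0088 reached 8689.9 ± 2276.4 CPM on hexacosanal against 962.2 ± 568.4 CPM on hexacosane. A lipase gene (bgh02747) was 7.97-fold higher and a phospholipase C gene (bgh02182) was higher by 2.93 ± 0.21. Among glycolysis genes, phosphoglycerate mutase (bgh05155), pyruvate kinase (bgh00037) and phosphofructokinase (bgh00033) were higher by 1.99 ± 0.12, 1.71 ± 0.11 and 1.54 ± 0.09, while a hexokinase (bgh01208) was lower, at −1.65 ± 0.14. The glycolysis list did not pass (camera adjusted p = 0.205), with 10 of 20 higher and 6 lower (10 and 6 adjusted over the list alone). Lower levels on hexacosanal were found for the Myb transcription factor bgh02243 (−2.15 ± 0.15), the CP2 transcription factor bgh04427 (−2.17 ± 0.25), a mechanosensitive ion channel (bgh01512, −1.93 ± 0.30) and cAMP-dependent protein kinase A (bgh02497, −1.61 ± 0.13). On hexacosanal bgh04427 and bgh01512 had only 4.4 ± 1.6 and 3.4 ± 2.1 CPM (SD).

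Of 5961 genes tested at 2 h, 3264 (54.8%) passed an adjusted p of 0.05 in edgeR, 1678 higher and 1586 lower on hexacosanal. Of these, 746 changed at least 2-fold, 461 higher and 285 lower. Under library totals the split became 912 higher and 2960 lower, or 23.6% higher in place of 51.4%. The 3 libraries of one surface lay entirely above those of the other for 3540 genes, 59.4% of those tested, where chance gives 10%.

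Gene lists fixed by words in the annotation differed between the surfaces at 2 h in opposite directions. Of 468 candidate secreted effectors, 59 were higher, 149 lower and 260 did not pass (59 and 144 adjusted over the list alone; 50 and 248 under library totals). Their median log2 difference was −0.35 (camera adjusted p = 0.00768; adjusted p = 0.479 with an estimated correlation). Single effectors went both ways, with CSEP0464 higher by 1.75 ± 0.13 and CSEP0451 lower, at −1.92 ± 0.23. Of 19 virulence and appressorium homologues, 13 were higher and 2 lower (13 and 2 adjusted over the list alone), with a mean of 1.09 (adjusted p = 0.0132; adjusted p = 0.479 with an estimated correlation). Removing the 20 most abundant genes also took members of this list and left 17, of which 11 were higher. The camera adjusted p rose to 0.0555 and the list median fell from 1 to 0.68, while the median of all genes stayed at −0.02. Members of the Egh16 and MAS1 families resemble each other and could share reads, so the values of bgh03318 (2.37 ± 0.21) and bgh04769 (3.13 ± 0.41) are uncertain. Of 30 genes of oxidative stress defence, 4 were higher and 17 lower (4 and 17 adjusted over the list alone; 2 and 24 under library totals). Their median was −0.36 (adjusted p = 0.0187; adjusted p = 0.479 with an estimated correlation), and they included mitochondrial peroxiredoxin PRX1 (bgh02344, −1.16 ± 0.09). Under library totals the medians of the effector and oxidative stress lists were −0.64 and −0.66. Relative to the median of all genes they hardly moved, from −0.33 to −0.32 for effectors and with −0.34 under either scaling for oxidative stress, but neither list passed camera (adjusted p = 0.482 and 0.0805).

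Of 92 genes of the secretory pathway, 45 were higher and 13 lower at 2 h (46 and 13 adjusted over the list alone; 24 and 33 under library totals). Their median was 0.23 and became −0.07 under library totals, which shift all genes alike, and was 0.25 above the median of all genes under either scaling (camera adjusted p = 0.00768; adjusted p = 0.479 with an estimated correlation; adjusted p = 0.0604 under library totals). The vesicle fusion genes SEC18 (bghG001382000001001), VTI1 (bgh00128) and SSO1 (bgh00125) were higher by 1.42 ± 0.09, 1.27 ± 0.10 and 1.06 ± 0.09. Of 119 genes in the list of cytosolic ribosomal proteins, 51 were higher and 9 lower (49 and 8 adjusted over the list alone; 11 and 30 under library totals). Their median was 0.26 and became −0.05 under library totals, but was 0.28 and 0.27 above the median of all genes under TMM and library totals (adjusted p = 0.00768; adjusted p = 0.735 with an estimated correlation; adjusted p = 0.263 under library totals). That list no longer passed without replicate 2 on hexacosanal at 2 h (adjusted p = 0.14) or without replicate 1 on hexacosane at 2 h (adjusted p = 0.0746). Its fixed word pattern also took mitochondrial ribosomal proteins. Genes of fatty aldehyde, alkane and alcohol metabolism, the list nearest to the chemistry of the surfaces, did not pass as a list at 2 h, with 6 of 32 higher and 15 lower (7 and 17 adjusted over the list alone; adjusted p = 0.205). Cutinases and lipases did not pass either (adjusted p = 0.849), with 11 of 39 higher and 12 lower (11 and 13 adjusted over the list alone; 9 and 21 under library totals), a median of −0.17 and a mean of 0.23.

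The comparison at 4 h 45 min asked how the surfaces differed later in the prepenetration phase. The candidate effector CSEP0039 (contig HF943526, 531449 to 532433) was 10.03-fold higher on hexacosanal (log2 difference 3.33 ± 0.17 SE, adjusted p = 3.37e-09, n = 3 per group), at 558.9 ± 99.6 CPM (SD) against 56.1 ± 8.4 CPM. The Egh16 and Gas1 homologue bgh01420, uncertain as said, was 7.09-fold higher (2.83 ± 0.13, adjusted p = 1.85e-09), with 764.8 ± 23.5 CPM against 108.1 ± 11.6 CPM. A gene for a chitin synthase export chaperone (bgh02019), which helps chitin synthase leave the endoplasmic reticulum, was higher by 3.05 ± 0.35, and a class III chitin synthase (bgh00822) by 1.54 ± 0.11. The glyoxal oxidase bgh00311 was again lower on hexacosanal, at −2.16 ± 0.11 (adjusted p = 3.24e-09), at 844.2 ± 89.8 CPM against 3767.8 ± 216.3 CPM.

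A cytochrome P450 monooxygenase (bgh01041) was lower at 4 h 45 min, at −2.41 ± 0.13 (SE, n = 3 per group), at 361.3 ± 47.2 CPM (SD) against 1925.8 ± 73.1 CPM. A lipase B precursor (bgh00973, −2.22 ± 0.13), an alpha-mannosidase (bgh00763, −2.26 ± 0.14), the hexokinase bgh01208 (−2.22 ± 0.14), glycogen phosphorylase (bgh00234, −1.90 ± 0.14) and the putative carbon catabolite repressor bgh00964 (−2.03 ± 0.11) were also lower. Trehalose-6-phosphate synthase (bghG001634000001001), a MAP kinase kinase kinase (bgh00354) and SpaA (bgh03512), named after a polarity protein of other fungi, were higher by 1.93 ± 0.12, 1.93 ± 0.11 and 1.73 ± 0.10. None of the lists of glycolysis, of glycogen and trehalose metabolism or of cutinases and lipases passed (camera adjusted p = 0.383, 0.671 and 0.671). They had 11 of 20, 3 of 12 and 16 of 39 genes higher and 6, 5 and 9 lower, and equal counts adjusted over the list alone. Under library totals 8, 2 and 12 were higher and 9, 6 and 17 lower. Further effectors that were higher included CSEP0037 (2.59 ± 0.14) and CSEP0278 (2.48 ± 0.10), while CSEP0339 and CSEP0240 were lower, at −2.90 ± 0.38 and −2.23 ± 0.21. On hexacosanal CSEP0339 had only 2.3 ± 2.6 CPM (SD). Large increases were found for bgh03059, a Mas1 homologue (3.40 ± 0.43), bgh01944, a MAS3 homologue (3.12 ± 0.33), and an EKA-like gene (bghG003307000001001, 3.13 ± 0.31). These belong to families whose members could share reads. A SANT domain protein (bgh04658) and a peptidase of family M20 (bgh04367) were higher by 3.20 ± 0.51 and 3.14 ± 0.35.

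At 4 h 45 min, 3759 of 5961 genes (63.1%) passed an adjusted p of 0.05 in edgeR, 1989 higher and 1770 lower on hexacosanal. Of these, 1092 changed at least 2-fold, 620 higher and 472 lower. Under library totals 1030 were higher and 3198 lower, 24.4% higher in place of 52.9%. The libraries of the surfaces did not overlap for 4179 genes, 70.1% of those tested, where chance gives 10%.

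Candidate effectors had a lower median at 4 h 45 min as well, −0.47, with 73 of 468 higher and 190 lower (72 and 181 adjusted over the list alone; 55 and 276 under library totals; camera adjusted p = 0.00233; adjusted p = 0.284 with an estimated correlation). Virulence and appressorium homologues had a median of 1.43, with 13 of 19 higher and 1 lower (13 and 2 adjusted over the list alone; 13 and 4 under library totals; adjusted p = 0.00607; adjusted p = 0.284 with an estimated correlation). Of 30 oxidative stress genes, 5 were higher and 19 lower (5 and 19 adjusted over the list alone), with a median of −0.55 (adjusted p = 0.0195; adjusted p = 0.284 with an estimated correlation). Glutathione peroxidase Gpx1 (bgh00083) went against that list at 1.57 ± 0.12, whereas PRX1, peroxiredoxin-5 (bgh00792) and a glutathione S-transferase (bgh01779) were lower, at −1.45 ± 0.09, −1.04 ± 0.09 and −1.83 ± 0.18. Genes of fatty aldehyde, alkane and alcohol metabolism were lower in 18 and higher in 6 of 32 cases (18 and 6 adjusted over the list alone), with a median of −0.49 (adjusted p = 0.0354; adjusted p = 0.284 with an estimated correlation). Under library totals these effector, oxidative stress and fatty aldehyde lists did not pass (adjusted p = 0.366, 0.254 and 0.276).

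Of 92 secretory pathway genes, 54 were higher and 12 lower at 4 h 45 min (54 and 12 adjusted over the list alone; 29 and 32 under library totals). Their median was 0.31 and became −0.08 under library totals, but was 0.29 above the median of all genes under either scaling (camera adjusted p = 0.00233; adjusted p = 0.284 with an estimated correlation). VTI1, SSO1 and the coatomer subunit delta (bgh02777) were higher by 1.89 ± 0.10, 1.71 ± 0.09 and 0.98 ± 0.07. Of 46 DNA replication genes, 22 were higher and 5 lower (22 and 5 adjusted over the list alone; 12 and 16 under library totals), among them mcm6 (bgh05549, 1.10 ± 0.09) and the SLD3 domain gene bgh06760 (1.14 ± 0.09). The list median was 0.22 and became −0.17 under library totals, but was 0.20 above that of all genes under either scaling (adjusted p = 0.0372; adjusted p = 0.284 with an estimated correlation; adjusted p = 0.357 under library totals). The list of cytosolic ribosomal proteins had 56 of 119 higher and 10 lower (54 and 10 adjusted over the list alone; 14 and 43 under library totals). Their median was 0.23 and became −0.16 under library totals, but was 0.21 above that of all genes under either scaling (adjusted p = 0.0354; adjusted p = 0.859 with an estimated correlation; adjusted p = 0.499 under library totals). Without replicate 2 on hexacosane at 4 h 45 min, neither the ribosomal list (adjusted p = 0.0765) nor the DNA replication list (adjusted p = 0.0556) passed.

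Across both times, 1377 genes were higher on hexacosanal at 2 h and again at 4 h 45 min, where 559.9 would be so if the calls were independent, and 1218 were lower at both, where 470.9 would be. Another 72 genes passed in opposite directions, 30 higher at 2 h and lower later and 42 the other way round. The log2 differences at both times, which share no library, correlated across genes at r = 0.854 and rho = 0.821. With both times averaged, 4198 genes (70.4%) passed in edgeR, 2164 higher and 2034 lower. Under library totals these were 1088 and 3571, 23.4% higher in place of 51.5%. At least a 2-fold average difference was found for 847 genes, 507 higher and 340 lower, and the surfaces did not overlap at either time, in the same direction at both, for 2769 genes, 46.5% of those tested, where chance gives 0.5%.

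Among genes with an informative name, the averaged effect was largest for the aquaporin bgh00516 (3.23 ± 0.33 SE, n = 6 per surface, adjusted p = 5.27e-07). Among genes without one, it was large for bghG000024000001001 (3.25 ± 0.26) and bgh02878 (−2.73 ± 0.12). The autophagy kinase gene ATG1 (bgh04721), an aspartic protease (bgh06756), methionyl-tRNA synthetase (bgh03276) and pyrroline-5-carboxylate reductase (bgh02840) were higher by 1.89 ± 0.08, 2.10 ± 0.11, 2.11 ± 0.13 and 1.87 ± 0.11. An integral membrane protein gene (bgh04008) was lower, at −2.39 ± 0.10 (adjusted p = 7.55e-11) and the glyoxal oxidase at −1.91 ± 0.08 (adjusted p = 7.55e-11). Averaged over both times, 5 lists passed. Candidate effectors were higher in 76 and lower in 223 of 468 cases (76 and 221 adjusted over the list alone; 52 and 318 under library totals; the other 4 lists had equal counts adjusted over the list alone), with a median of −0.42 (camera adjusted p = 0.00214; adjusted p = 0.286 with an estimated correlation). Oxidative stress genes were higher in 6 and lower in 19 of 30 cases (3 and 22 under library totals; median −0.57, adjusted p = 0.0153; adjusted p = 0.345 with an estimated correlation). Virulence homologues were higher in 13 and lower in 3 of 19 cases (median 1.05, adjusted p = 0.00919; adjusted p = 0.345 with an estimated correlation). The secretory list (57 of 92 higher, 18 lower; 34 and 38 under library totals; adjusted p = 0.00285; adjusted p = 0.345 with an estimated correlation) and the ribosomal list (73 of 119 higher, 11 lower; 18 and 46 under library totals; adjusted p = 0.00805; adjusted p = 0.837 with an estimated correlation) each had a median of 0.26 that became −0.09 under library totals, 0.26 above that of all genes under either scaling. Under library totals the effector, oxidative stress and ribosomal lists did not pass (adjusted p = 0.369, 0.16 and 0.445).

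**Figure D2:**
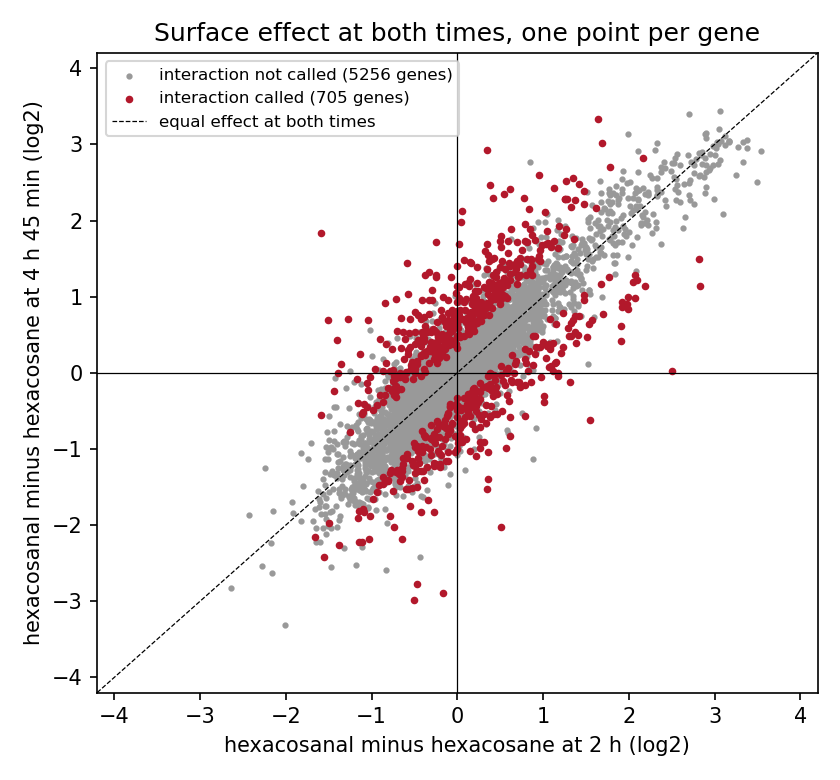
Log2 difference of hexacosanal minus hexacosane at 2 h (horizontal) and at 4 h 45 min (vertical), 1 point per gene, TMM scaling; red points are the 705 genes whose difference changed with time. The dashed line marks equal differences at both times, and library totals would move all points by −0.31 horizontally and −0.39 vertically.

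The time comparison on hexacosanal asked what changed between 2 h and 4 h 45 min on the inductive surface. The effector genes CSEP0037 and CSEP0039 rose by 2.64 ± 0.14 (SE, adjusted p = 1.15e-08, n = 3 per time) and 2.12 ± 0.16, the first from 72.8 ± 17.1 (SD) to 451.4 ± 45.2 CPM. An exochitinase gene (bgh05545) rose by 1.59 ± 0.09 (adjusted p = 1.56e-08), from 241.1 ± 25.7 to 727.4 ± 29.3 CPM, and an extracellular chitinase (bgh00588) by 2.17 ± 0.13. The homologue of Egh16 and Gas1, bgh01420, also uncertain here, rose by 1.55 ± 0.12. A gene for kinase Sgk2 (bghG007957000001001), from a family with many copies, fell from 529.7 ± 48.8 to 81.8 ± 15.7 CPM (−2.70 ± 0.13, adjusted p = 7.01e-09).

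Among the informatively named genes that met the naming rule, a C2H2 zinc finger gene rose most on hexacosanal (bgh06523, 3.98 ± 0.43 SE, n = 3 per time). It had only 1.1 ± 1.1 CPM (SD) at 2 h and 18.4 ± 3.9 CPM at 4 h 45 min, so the size of its rise is uncertain. The SANT domain gene bgh04658 rose by 3.32 ± 0.52, from 92.6 ± 73.2 (SD) to 909.3 ± 127.1 CPM. The membrin gene (bgh04544), for a SNARE of the Golgi, rose 6.05-fold, CSEP0185 by 2.30 ± 0.33 and the RMD8 homologue bgh01391 by 2.24 ± 0.20. The falls included those of an omega-3 fatty acid desaturase (bgh01504, −2.10 ± 0.15), a subunit of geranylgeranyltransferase (bgh00943, −2.03 ± 0.11), the sterol gene Erg25 (bgh00887, −1.47 ± 0.10), glutathione synthetase (bgh00071, −1.88 ± 0.17) and the NADH kinase POS5 (bgh03519, −1.91 ± 0.15). The list of fatty acid, sterol and sphingolipid synthesis did not pass (camera adjusted p = 0.939), with 17 of 62 higher and 20 lower (19 and 21 adjusted over the list alone). Neither did oxidative stress defence (adjusted p = 0.662), with 5 of 30 higher and 9 lower (5 and 9 adjusted over the list alone). A bZIP factor of the AP-1 type (bgh00909) fell by 1.67 on the log2 scale (SE 0.35), CSEP0339 fell by 2.64 (SE 0.40) and bgh02784, a 30 kDa heat shock protein gene with similar copies, by 2.43 (SE 0.51). At 4 h 45 min bgh00909 and CSEP0339 had only 3.7 ± 2.9 and 2.3 ± 2.6 CPM (SD). Among genes that met the naming rule, bghG004129000002001, without an informative name, fell most, by 3.44 (SE 0.32).

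On hexacosanal 2276 of 5961 genes (38.2%) passed over time in edgeR, 1207 higher and 1069 lower at 4 h 45 min. Of these, 357 changed at least 2-fold, 236 higher and 121 lower. Under library totals 920 were higher and 1498 lower, 38% higher in place of 53%. The times did not overlap for 2789 genes, 46.8% of those tested, where chance gives 10%. Of 19 virulence and appressorium homologues, 10 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.00349; adjusted p = 0.616 with an estimated correlation). Of 75 ribosome biogenesis genes, 4 rose and 28 fell (4 and 28 adjusted over the list alone), with a median of −0.21 (adjusted p = 0.00349; adjusted p = 0.616 with an estimated correlation). The pre-rRNA processing gene Esf1 (bgh03919) and UTP10 (bgh00882) fell by 0.93 and 0.89 on the log2 scale (SE 0.12 each). Oxidative phosphorylation genes fell in 21 and rose in 4 of 84 cases (21 and 4 adjusted over the list alone; 34 and 4 under library totals; median −0.14, adjusted p = 0.0359; adjusted p = 0.946 with an estimated correlation). Genes of the tricarboxylic acid cycle fell in 10 and rose in 2 of 27 cases (12 and 2 adjusted over the list alone; 15 and 1 under library totals; median −0.22, adjusted p = 0.0421; adjusted p = 0.616 with an estimated correlation). In the latter list malate dehydrogenase (bgh01918) fell by 1.11 on the log2 scale (SE 0.11), while aconitase ACO1 (bgh00068) rose by 0.77 ± 0.11.

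The oxidative phosphorylation list no longer passed without replicate 2 at 2 h (adjusted p = 0.228) or without replicate 3 at 4 h 45 min on hexacosanal (adjusted p = 0.0767). The tricarboxylic acid cycle list no longer passed without replicate 3 at 2 h (adjusted p = 0.135), replicate 1 at 4 h 45 min (adjusted p = 0.0541) or replicate 3 at 4 h 45 min (adjusted p = 0.0813). Candidate effectors did not pass as a list over time on hexacosanal (adjusted p = 0.939), with 56 of 468 higher and 41 lower (43 and 27 adjusted over the list alone; 43 and 54 under library totals, which shift all genes alike), and a median of −0.03 and −0.02 relative to all genes under TMM and library totals.

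The time comparison on hexacosane gave the changes on the surface called non-inducing. A Ser/Thr phosphatase gene (bgh03627) rose from 1157.9 ± 163.8 (SD) to 2625.7 ± 258.7 CPM (log2 change 1.18 ± 0.16 SE, adjusted p = 0.00135, n = 3 per time). The homologue bgh01420, with the same uncertainty, and the effector CSEP0037 rose here too, 1.84-fold and 2.002-fold (adjusted p = 0.00361 for each). The gene for the alpha subunit of SEC61 (bgh03494), the channel through which proteins enter the endoplasmic reticulum, fell from 265.4 ± 28.9 to 155.2 ± 8.4 CPM (−0.78 ± 0.09, adjusted p = 0.000718). Acetylglutamate synthase (bgh00388), a long-chain acyl-CoA ligase (bghG004751000001001) and malate dehydrogenase (bgh01918) fell by 1.22, 1.02 and 0.91 on the log2 scale (SE 0.15, 0.11 and 0.12).

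Further rises on hexacosane were those of the effector-like gene CELP0012 (1.39 ± 0.23 SE, n = 3 per time), the transcription factor NsdD (bgh03088, 0.65 ± 0.11) and cAMP-dependent protein kinase A (bgh02497, 0.65 ± 0.11). The MAS1 family member bgh03318, uncertain for the reason given above, rose by 1.19 ± 0.20. The largest rises, of the SANT domain gene bgh04658 (3.17 ± 0.65) and of the Mas1 homologue bgh03059 (2.42 ± 0.49), did not pass without replicate 3 on hexacosane at 2 h (adjusted p = 0.0675 and 0.0643) or without replicate 1 at 4 h 45 min (adjusted p = 0.0599 and 0.0557), and limma-voom gave an adjusted p of 0.0783 for the first.

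On hexacosane 343 of 5961 genes (5.8%) passed over time in edgeR, 182 higher and 161 lower at 4 h 45 min, and 26 changed at least 2-fold, 21 higher and 5 lower. The number depended on single libraries: it was 99 without replicate 3 at 2 h, and 63, 103 and 170 without replicates 1, 2 and 3 at 4 h 45 min. A fit of these 6 libraries alone gave 549 genes. The times did not overlap for 1788 genes, 30% of those tested, where chance gives 10%. Of 92 secretory pathway genes, 5 fell and 0 rose in edgeR (11 and 0 adjusted over the list alone; 8 and 0 under library totals), with a median of −0.12 (camera adjusted p = 1.5e-05; adjusted p = 0.343 with an estimated correlation). Of 19 virulence and appressorium homologues, 5 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.43 (adjusted p = 0.000507; adjusted p = 0.343 with an estimated correlation). Of 84 oxidative phosphorylation genes, 5 fell (5 adjusted over the list alone), with a median of −0.10 (adjusted p = 0.000287; adjusted p = 0.516 with an estimated correlation).

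Another 4 lists passed on hexacosane with median changes between −0.10 and 0.08 and depended on single libraries. They were cytosolic ribosomal proteins (adjusted p = 0.0419), mitochondrial ribosomal proteins (adjusted p = 0.0419), the tricarboxylic acid cycle (adjusted p = 0.0419) and transcription factors (adjusted p = 0.0442), with 1 of 119, 1 of 27, 4 of 27 and 2 of 153 genes lower and 7 transcription factors higher. Adjusted over the list alone, 1, 1, 6 and 2 were lower and 8 transcription factors higher. With an estimated correlation these had an adjusted p of 0.802 for cytosolic ribosomal proteins and of 0.343 for each of the others. Neither ribosomal list passed without replicate 2 at 2 h on hexacosane (adjusted p = 0.457 and 0.0754), replicate 3 at 2 h (0.137 and 0.146) or replicate 2 at 4 h 45 min (0.173 and 0.111). The tricarboxylic acid cycle list did not pass without replicates 1 or 2 at 2 h (adjusted p = 0.0815 and 0.0913) or replicate 3 at 4 h 45 min (0.0737). Transcription factors did not pass without replicates 1, 2 or 3 at 2 h (adjusted p = 0.06, 0.102 and 0.0529) or replicate 2 at 4 h 45 min (0.198), and neither without a filter on low counts (0.0569) nor without the 20 most abundant genes (0.0566).

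**Figure D3:**
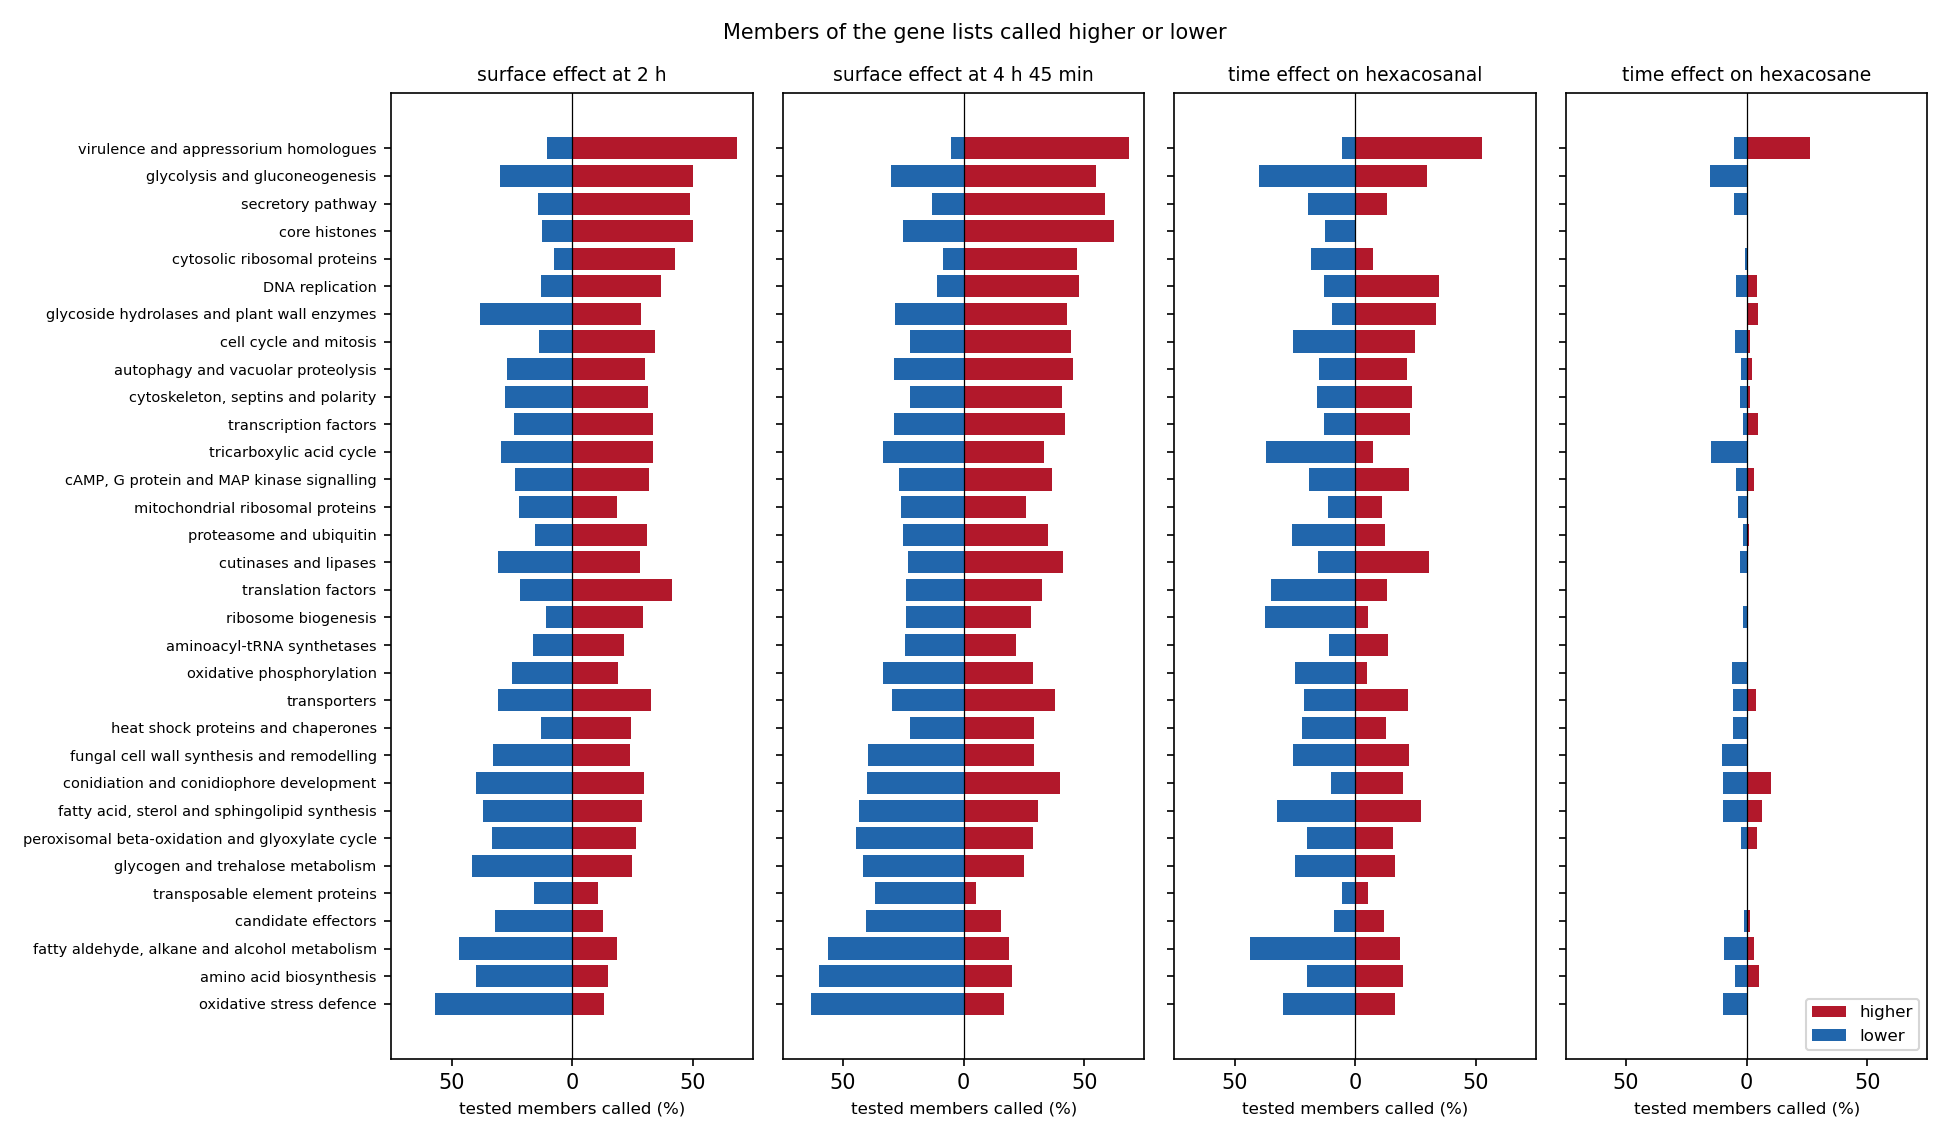
Percent of the tested members of each gene list called higher (red, to the right) or lower (blue, to the left) in 4 comparisons under TMM scaling; each bar is a list. Under library totals the share called higher over all genes fell from 51.4% to 23.6% at 2 h and from 52.9% to 24.4% at 4 h 45 min, and the medians of the secretory and ribosomal lists turned negative in both surface panels. Relative to all genes these medians stayed positive under library totals, at 0.25 and 0.27 at 2 h and 0.29 and 0.21 at 4 h 45 min.

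The interaction asked whether the difference between the surfaces changed with time, which is the same as whether the change with time differed between the surfaces. The exochitinase bgh05545 rose more on hexacosanal than on hexacosane (interaction 1.61 ± 0.12 SE, adjusted p = 5.67e-06, n = 3 per group). On hexacosane its means were 358.1 ± 19.2 (SD) and 353.5 ± 7.3 CPM. The extracellular chitinase bgh00588 and the effectors CSEP0039 and CSEP0037 also gained more on hexacosanal, by 2.03 ± 0.19 (adjusted p = 2.26e-05), 1.69 ± 0.25 and 1.64 ± 0.21. The kinase Sgk2 gene bghG007957000001001 fell more on hexacosanal (−2.17 ± 0.18, adjusted p = 1.23e-05), with 181.1 ± 21.5 and 126.3 ± 13.7 CPM on hexacosane. The omega-3 fatty acid desaturase bgh01504, the glutaminase GtaA (bgh03308) and the short-chain dehydrogenase bgh00604 had interaction values of −1.75 ± 0.21, −1.40 ± 0.13 and −1.20 ± 0.13.

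In edgeR, 705 of 5961 genes (11.8%) passed for the interaction, 399 with a more positive surface difference at 4 h 45 min and 306 with a more negative one. Of these, 148 did so by at least 2-fold, 92 and 56. Under library totals 288 were more positive and 426 more negative, 40.3% in place of 56.6%. The changes with time on both surfaces, which share no library, correlated across genes at r = 0.577 and rho = 0.522. On both surfaces 142 genes rose and 118 fell, where 36.9 and 28.9 would do so if the calls were independent. Ribosome biogenesis was the 1 list that passed, with 0 of 75 genes more positive and 5 more negative (0 and 5 adjusted over the list alone; 0 and 9 under library totals), a median of −0.19 and an adjusted p of 0.0305 (adjusted p = 0.914 with an estimated correlation). It did not pass on hexacosanal without replicate 3 at 2 h (adjusted p = 0.13) or replicates 1 or 2 at 4 h 45 min (0.105 and 0.0717), nor on hexacosane without replicate 2 at 2 h (0.167) or replicates 2 or 3 at 4 h 45 min (0.0788 and 0.0715). Candidate effectors did not pass as a list (adjusted p = 0.7), with 13 of 468 more positive and 13 more negative (6 and 6 adjusted over the list alone; 9 and 14 under library totals).

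**Figure D4:**
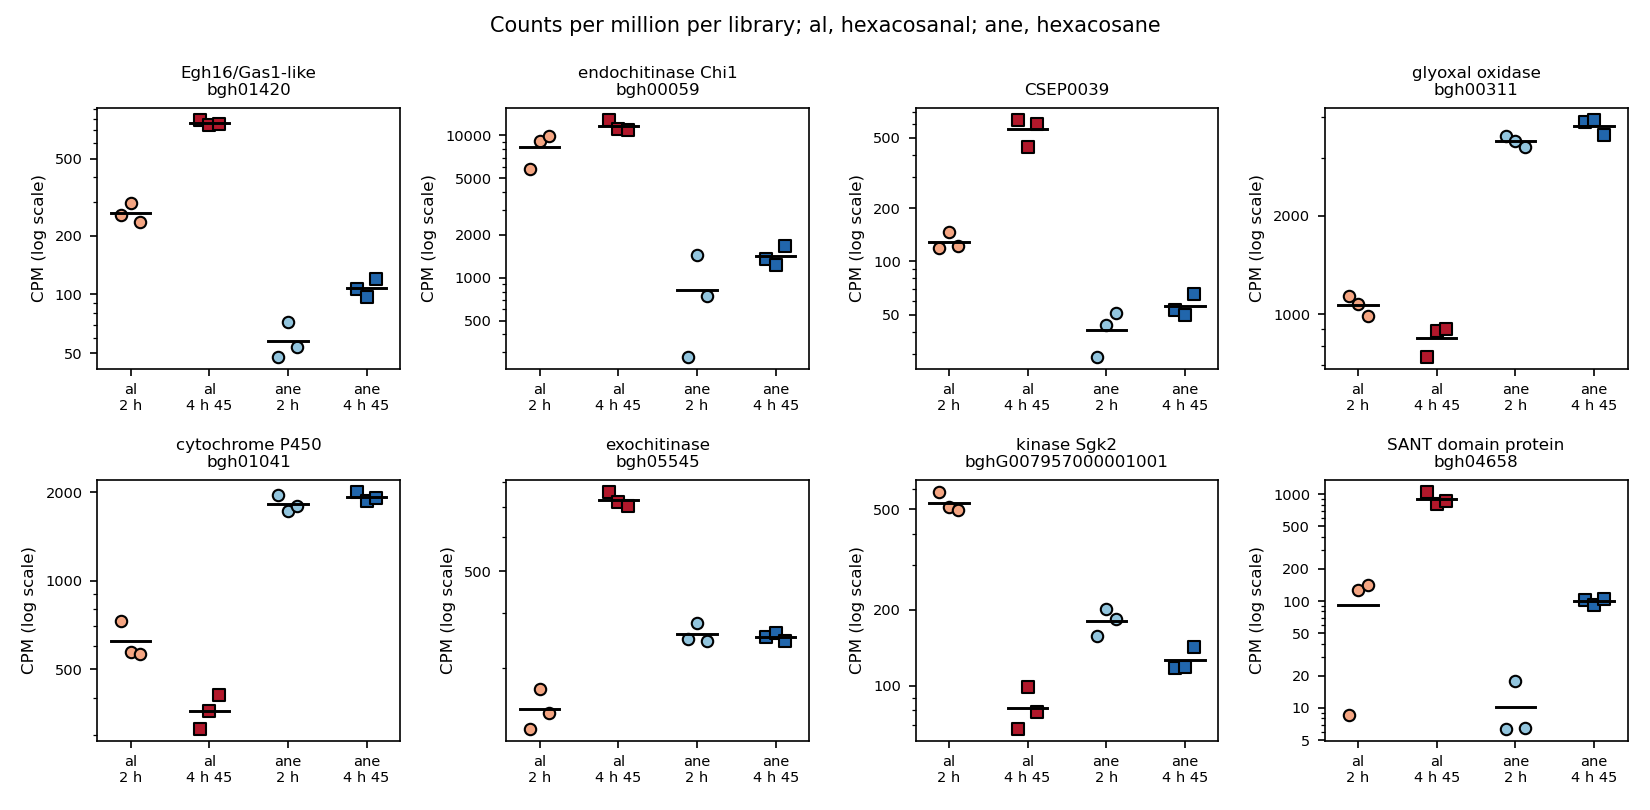
CPM (log scale) of 8 genes named in the text in each of the 12 libraries; points are libraries, bars are means of 3, and al and ane stand for hexacosanal and hexacosane. CPM use TMM-scaled library sizes; bgh01420 lay highest on hexacosanal at 4 h 45 min (764.8 CPM) and the glyoxal oxidase bgh00311 on hexacosane (3378.7 and 3767.8 CPM).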

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

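The tests of the size of changes on both surfaces, of the library between the surfaces and of other splits were chosen after the numbers of genes changed over time had been seen; the interaction test, its lists, limma-voom and the libraries left out were planned. The difference between the surfaces changed with time for 705 genes and 1 list, ribosome biogenesis (camera adjusted p = 0.0305; adjusted p = 0.914 with an estimated correlation), by the interaction test, and this difference between groups is what drew attention to them. Positive interaction values, in log2 units, were found for a C2H2 zinc finger gene (bgh06523, 3.43), the flap endonuclease bgh02017 (2.21), membrin (bgh04544, 2.09), the extracellular chitinase bgh00588 (2.03) and the exochitinase bgh05545 (1.61). Others were adenine phosphoribosyltransferase (bgh00683, 1.94), the effectors CSEP0039 and CSEP0037 (1.69 and 1.64), the GTPase-activating gene bgh04514 (1.69), a cell division cycle gene (bgh00349, 1.68), a kinase Sgk2 gene (bghG000116000001001, 1.67), the Egh16 family members bgh04088 and bgh01420 (0.94 and 0.67) and the unnamed bgh04647 (2.58). Negative values were found for the effector CSEP0339 (−2.73), the unnamed bghG004129000002001 (−2.48), another Sgk2 gene (bghG007957000001001, −2.17), the candidate effector bgh01194 (−1.87), the omega-3 desaturase bgh01504 (−1.75) and the PX domain gene bgh01501 (−1.49). The list continued with a glutathione S-transferase (bgh01779, −1.41), glutaminase GtaA (bgh03308, −1.40), Ytm1 (bgh03645, −1.40) and the short-chain dehydrogenase bgh00604 (−1.20). Negative interaction values of smaller size were those of the ribosome biogenesis genes UTP10 (bgh00882, −0.73), Esf1 (bgh03919, −0.67), bgh03606 (−0.64) and IMP3 (bgh02381, −0.61). Sgk2 and Egh16 genes have similar copies, so their values are uncertain. The values of bgh06523 and bgh02017 rest on only 1.1 ± 1.1 and 2.9 ± 0.8 CPM (SD) on hexacosanal at 2 h. That of CSEP0339 rests on 2.3 ± 2.6 CPM there at 4 h 45 min.

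Some of these calls rested on single libraries. The call of bgh01420 was lost without replicate 3 at 2 h, replicates 1 or 3 at 4 h 45 min on hexacosanal, replicate 2 at 2 h or replicates 1 or 2 at 4 h 45 min on hexacosane (adjusted p in edgeR from 0.0524 to 0.0811). That of bgh00349 was lost without replicates 1 or 3 at 4 h 45 min on hexacosanal, replicate 1 at 2 h or replicate 2 at 4 h 45 min on hexacosane (0.051 to 0.0545), and that of bgh04647 without replicates 2 or 3 at 2 h or replicate 2 at 4 h 45 min on hexacosane (0.0515 to 0.0637). The calls of bgh04544 without replicate 2 and of bgh04088 without replicate 3 on hexacosane at 2 h were lost too (0.0661 and 0.0548), as was that of bgh03919 without replicate 1 on hexacosanal at 4 h 45 min (0.052). In limma-voom bgh00349 and bgh04647 did not pass (0.0515 and 0.0912). Ribosome biogenesis was lost as a list without any of 6 libraries, with adjusted p from 0.0715 to 0.167, as given with the interaction results.

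More genes changed over time on hexacosanal (2276) than on hexacosane (343). If the changes had been equal in size and only measured less precisely on hexacosane, the genes called on both surfaces in the same direction should have been larger on either surface about equally often; of 260 such genes, 78.5% changed more on hexacosanal, which argues against that explanation. The library that lay between the surfaces, replicate 1 on hexacosanal at 2 h, did not account for the larger number on hexacosanal. Without that library 2212 genes still passed over time on hexacosanal, and 751 passed for the interaction. A hypothesis that stays open is that the inductive surface drives a larger change between the times; a different share of responding conidia per library may contribute and was not separated from it.

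Other splits of the libraries were counted for the interaction by exchanging surface labels within each time, with 100 of 200 distinct splits drawn. In 8 of the 100, the real one included, at least 705 genes passed, the highest other being 4198, so this count does not exclude chance. The other 7 all exchanged 2 or 3 surface labels at 1 of the times and at most 1 at the other. In these 7 the exchange turned much of the surface effect into an interaction and so reflects the separation of the libraries by surface. Most such splits gave few genes or 0. Those drawn with 2 labels exchanged at 1 time and 1 at the other gave 0. Those with 2 exchanged at 4 h 45 min and 0 at 2 h gave from 14 to 86. Large counts came with 3 labels exchanged at 4 h 45 min, or with 2 at 2 h and 0 at 4 h 45 min. The highest count among the splits without such an exchange was 169. For the lists, 88 of 100 splits gave at least 1, the highest other being 7, so chance was not excluded for the ribosome biogenesis list.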

How the results depend on the processing

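The narrowed and split lists were chosen after seeing the data; the other alternatives were planned. No named gene reversed in any setting: of 1977 values for 204 pairs of a gene and a comparison under the alternatives other than the fold minimum and leaving out libraries, 1971 kept their call and 6 lost it. With a minimum of 2-fold 167 of 204 kept it, and over 1500 values with a library left out 1431 did and 69 did not. Named genes were largely picked for large changes or small p, so reversals among them were unlikely. Over all genes, library totals turned 13 calls for the surface at 4 h 45 min and 128 for the average to the opposite direction. For the surface at 2 h, at 4 h 45 min and on average, 766, 946 and 948 calls were lost. Across DESeq2 size factors, library totals, the DESeq2 Wald test, limma-voom, both filters, unrounded values and removal of the 20 most abundant genes, the number of genes passing stayed between 3061 and 3872 for the surface at 2 h, 3449 and 4228 at 4 h 45 min, 2142 and 2418 over time on hexacosanal, 331 and 387 over time on hexacosane, 682 and 714 for the interaction, and 3839 and 4659 for the average. A minimum of 2-fold left 746, 1092, 357, 26, 148 and 847 genes in the same order, by construction, since it removes the smaller changes. A fit of only the groups compared gave 2897 genes at 2 h, 3955 at 4 h 45 min, 1958 over time on hexacosanal and 549 over time on hexacosane, where the dispersion came from the 6 libraries alone; the cause was not tested further, and for the interaction and the average this fit is the one reported. Replicate number as a block gave 3246, 3712, 2234, 324, 667 and 4182 genes. Whether equal numbers pair the libraries stays open. Deviations of equal numbers from their group means correlated between −0.181 and 0.43 across genes. Between the surfaces at 2 h these values were 0.43, 0.35 and −0.037 for replicates 1 to 3. Replicates 1 and 2 on hexacosanal at 2 h correlated best with their own number there and replicate 3 did not, and not every library did so in any pair of groups.

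Lists moved more. With library totals 1, 2 and 2 lists passed at 2 h, at 4 h 45 min and on average, in place of 5, 7 and 5; medians relative to all genes hardly moved, and the cause was not tested. With the correlation estimated from the residuals 0 lists passed in any comparison, while camera with the preset correlation passed 5, 7, 4, 7, 1 and 5. The order is 2 h, 4 h 45 min, time on hexacosanal, time on hexacosane, interaction and average. Camera also uses fewer degrees of freedom when it estimates the correlation, so the loss cannot be put down to the correlation alone. The fry rotation test, which does not compare a list with other genes, passed 26, 21, 14, 6, 1 and 25 lists in the same order. It lost cytosolic ribosomal proteins at 4 h 45 min (adjusted p = 0.0613) and over time on hexacosane (0.609). Over time on hexacosane it also lost mitochondrial ribosomal proteins (0.102) and oxidative phosphorylation (0.114), which left 4 of 7 lists, and for the interaction it lost ribosome biogenesis (0.112). Replicate number as a block passed 5, 7, 4, 5, 1 and 5 lists and lost the tricarboxylic acid cycle and transcription factors over time on hexacosane (0.0516 for each). Narrowed patterns gave 6, 8, 4, 7, 1 and 6 lists, and families split into their own lists gave 6, 9, 4, 7, 1 and 7.

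Leaving out each library in turn moved the genes changed over time on hexacosane between 63 (without replicate 1 at 4 h 45 min) and 357 (without replicate 1 at 2 h), with 99 without replicate 3 at 2 h and 103 and 170 without replicates 2 and 3 at 4 h 45 min. The lists over time on hexacosane ranged from 3 (without replicate 2 at 2 h) to 7, with 4 without replicate 3 at 2 h or replicate 2 at 4 h 45 min. On hexacosanal they ranged from 2 (without replicate 3 at 4 h 45 min) to 5 (without replicate 1 at 2 h), and for the interaction from 0 to 1. The interaction genes ranged from 470 without replicate 1 on hexacosanal at 4 h 45 min to 751. Fewer libraries lower the power, and the part that this played was not tested. Summing sense and antisense reads and the antisense share of counts were not run, since only sense values were used here. In the simulated counts 74.6% of the genes changed 1.5-fold were recovered for the surface at 2 h and 40.3% for the interaction. Only a small share of the simulated genes was changed, while 54.8% and 11.8% of the real genes passed in these comparisons. The adjusted p depends on that share, so these recovery values do not carry over to the real data. How often smaller changes were missed there was not measured.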

Other observations

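The tests on shared levels, on the position of single libraries and shifts they share, and of other splits were chosen after the results had been seen, except the test of exchanged labels, whose bound was written before. Added lists, chosen after the descriptions were read, split the effectors into numbered and unnumbered candidates, and most genes of either list were not called at 2 h. At 2 h 86 of 256 numbered effectors were lower and 41 higher (86 and 41 adjusted over the list alone; 140 and 36 under library totals; camera adjusted p = 0.0127; adjusted p = 0.235 with an estimated correlation), and 55 of 158 unnumbered candidates were lower and 13 higher (51 and 13 adjusted over the list alone; 86 and 10 under library totals; adjusted p = 0.00222; adjusted p = 0.235 with an estimated correlation). At 4 h 45 min these were 105 lower and 54 higher (105 and 54 adjusted over the list alone; 144 and 40 under library totals; adjusted p = 0.0189; adjusted p = 0.25 with an estimated correlation), and 70 lower and 15 higher (66 and 15 adjusted over the list alone; 101 and 13 under library totals; adjusted p = 0.000501; adjusted p = 0.136 with an estimated correlation). Of 51 genes of the EKA and AVR family, whose similar copies could share reads, 15 were lower and 2 higher at 4 h 45 min (11 and 2 adjusted over the list alone; 30 and 1 under library totals; adjusted p = 0.0094; adjusted p = 0.362 with an estimated correlation).

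The signalling list as first fixed held many unrelated proteins and did not pass at 2 h (adjusted p = 0.559), with 187 of 589 higher and 140 lower (188 and 140 adjusted over the list alone; 90 and 278 under library totals, which shift all genes alike), and a median 0.06 above that of all genes under either scaling. Narrowed to cAMP, G protein and MAP kinase genes, 38 of 78 were higher and 17 lower at 2 h (40 and 18 adjusted over the list alone; 28 and 30 under library totals), with a median of 0.23 that became −0.08 under library totals and was 0.24 above that of all genes under either scaling (camera adjusted p = 0.0127; adjusted p = 0.235 with an estimated correlation). At 4 h 45 min 41 of the 78 were higher and 19 lower (42 and 19 adjusted over the list alone; 29 and 31 under library totals), with a median of 0.28 that became −0.11 under library totals and was 0.26 above that of all genes under either scaling (adjusted p = 0.0189; adjusted p = 0.25 with an estimated correlation). Amino acid biosynthesis did not pass at 4 h 45 min, with 4 of 20 genes higher and 12 lower (4 and 12 adjusted over the list alone; 2 and 14 under library totals; adjusted p = 0.197).

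Among genes with a mean of at least 20 CPM over the groups, the largest log2 difference between the surfaces was 3.54 at 2 h and 3.43 at 4 h 45 min, with 21 and 19 genes above 3. The largest falls among these genes were −2.64 and −2.82. A set of 79 genes higher on hexacosanal by at least 2.5 on the log2 scale (5.66-fold) at 4 h 45 min, taken from the same genes, was therefore followed on hexacosane. In the hexacosane libraries these genes had a median level of 8.21, 21.42 and 13.78% of that on hexacosanal for replicates 1 to 3 at 2 h, and 14.07, 12.53 and 16.19% at 4 h 45 min. The genes moved together. Of them, 97.5% were lower in replicate 1 than in replicate 2 on hexacosane at 2 h, against 55.9% of 4905 other genes. These replicates had the lowest and highest medians there, so a high share was foreseeable and adds little to the medians. The shared movement argues against low levels that vary independently from gene to gene. A share of hexacosanal-type RNA in each hexacosane library, from conidia that responded on hexacosane or from carried-over RNA, may explain a part of this. Other explanations were not tested. The slope of the time effect on hexacosane against that on hexacosanal was 0.49 ± 0.05 for these genes. For the others it was 0.30 ± 0.005. The value of 0.49 fell short of the bound set for such a share, but by less than its error, so it does not decide. Errors of the slopes are standard errors over genes, which are not independent, and do not measure the spread between libraries. On hexacosane at 2 h the 10th percentile of the gene ratios was 0.52, 0.84 and 0.60 of their median for replicates 1 to 3. At 4 h 45 min it was 0.81, 0.82 and 0.82. The picking at that time held those ratios, and the medians there, in a narrow range. The lowest single gene ratios on hexacosane at 2 h were 2.1, 16.23 and 5.44% for replicates 1 to 3. A share equal for all genes could hardly exceed them. In replicates 1 and 3 it could thus make up only a part of the medians. The lowest of the percentile values, 0.52, stayed above the bound set against carried-over RNA, so responding conidia and carried-over RNA could not be separated. Both stay open, and either would make the reported differences between the surfaces smaller than those between responding and resting conidia. A first version, run before the bound was set, picked 49 genes at 2 h, above 2.75 on the log2 scale, and gave a slope of 0.66 ± 0.04. That value would have met the bound, but the picking and the measuring shared the 2 h libraries. In the version reported, the picking and both time effects shared the 4 h 45 min libraries. Neither slope is therefore free of the picking, and neither decides whether there was such a share.

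Replicate 1 on hexacosanal at 2 h lay between the surfaces. On a scale with hexacosane at 0 and the other hexacosanal libraries at 2 h defining 1, its median position was 0.75, at 0.70 for 556 genes higher and 0.84 for 287 genes lower on hexacosanal, while replicates 2 and 3 were at 1.08 and 1.19. This is consistent with a mixed sample or a smaller share of responding conidia. A shift shared by libraries of equal number at 2 h stays open too: replicate 1 on hexacosane had the lowest position there, −0.10, and its deviation correlated with that of replicate 1 on hexacosanal at 0.43 across genes, but for replicate 3 this was −0.037. Exchanged labels within 2 h would need a hexacosane library near 1, but the highest such position was 0.10, which argues against it. The deviation of replicate 1 on hexacosanal also had a coefficient of 0.11 ± 0.009 towards 4 h 45 min beside 0.21 ± 0.005 towards hexacosane (r squared 0.22), so a different stage in time could not be separated. A first version took the surface direction from the 2 h libraries and gave −0.03 ± 0.008 towards 4 h 45 min beside 0.23 ± 0.005, which would have argued against a different stage. In both versions replicates 2 and 3 enter the deviation and the time direction, so the coefficient depends on the choice made. The errors of these coefficients are also taken over genes and do not measure the spread between libraries.

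Other splits of the 6 libraries were counted for each comparison of 2 groups. There are only 10 splits of 3 against 3, too few for a share under 0.05. The real split called 3264 genes for the surface at 2 h, 3759 at 4 h 45 min, 2276 over time on hexacosanal and 343 over time on hexacosane, each in 1 of 10 splits, and the highest other split called 0 in each. For the lists the real and highest other values were 5 and 6 at 2 h (2 of 10 splits with at least as many), 7 and 5 at 4 h 45 min (1 of 10), 4 and 4 over time on hexacosanal (2 of 10), and 7 and 5 over time on hexacosane (1 of 10). For the surface averaged over both times, 1 of 100 splits drawn gave 4198 genes, the real one, and the highest other gave 2518. That other split exchanged 2 surface labels at 2 h and 3 at 4 h 45 min, so it was close to a reversal of the real one. The number of genes thus argues against chance for these libraries but does not exclude it. For its 5 lists, 14 of 100 splits gave at least as many, with a highest other of 7, so chance was not excluded.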
